A study of Mus musculus with 9 samples.

How the data were processed

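RNA of 9 sorted samples was labelled with Cy3, 0.5 µg each, and hybridised to 1-colour Agilent mouse arrays of design 026655, 3 arrays each for naive, Th1 and Th17 cells. Per the labels, the cells were magnetically enriched for CD4, stimulated for 3 h with PMA (10 ng/ml) and ionomycin (500 ng/ml), and sorted after secreted IL-17A and interferon gamma had been captured on their surface. The array barcodes place the 3 naive arrays and Th1 replicate 1 on slide 1, Th1 replicates 2 and 3 with Th17 replicates 1 and 2 on slide 2, and Th17 replicate 3 on slide 3, so no slide held naive and Th17 cells together.

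The deposited array files hold the processed signal of each spot as an intensity on a linear scale, background-subtracted and spatially detrended by Agilent Feature Extraction, with no normalization between arrays. They also hold the raw median intensity of the spot and of its local background. The file headers give Feature Extraction version 10.7.3.1 and the authors' notes give version 10.5. The table deposited by the authors holds log2 values, which match the log2 intensity shifted to the 75th percentile of each array minus a constant per probe, whose baseline is not stated. The header names an older genome build than the reference at hand, so annotation was used for gene names only, and no positions are given. The files carried no gene names. Symbols were assigned through RefSeq accessions to 27234 of 39429 probes. The 12195 probes without one were kept under the sequence name the array design gives, often a transcript identifier. Some of these may be transcripts of genes that were also tested under a symbol.

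Each array had 44397 spots, of which 1377 were controls. Controls and spots marked as outliers were left out, log2 of the processed signal was shifted to the 75th percentile of the array, and spots of a probe were averaged. Probes were kept where well above background on at least 3 of the 9 arrays (23215 probes), and the brightest probe stood for each gene, which left 19071 genes. Between 53.4% and 58.3% of probes were well above background on an array. The number of arrays limits the precision. Where no array of a group was well above background, a change is given as a lower bound against the lowest signal among probes above background, and no fold is given where both groups lay below it. Among the called genes 24, 13 and 5 had no array above background in either group of Th1 against naive, Th17 against naive and Th17 against Th1.

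The 3 groups were fitted together with limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table and moderated variances from eBayes, and each pair was contrasted. A gene was called at a two-sided adjusted p under 0.05 (Benjamini-Hochberg over the genes tested). Replicate numbers are not said to mark shared animals, so no pairing was used. Residuals of arrays of different groups had a Pearson r across genes of -0.007 to 0.175 with the same number and of -0.197 to 0.065 with different numbers, and a replicate block was among the alternatives. Gene lists were tested against all other genes with camera at a preset correlation of 0.01, adjusted over the 33 lists with at least 3 measured genes, and again with an estimated correlation. With the estimate, 1 list passed in Th1 against naive cells, the inhibitory receptors, and 0 in each of the other comparisons. The p-value of that list rose although its estimate lay below 0.01. Values with an estimated correlation therefore do not measure the effect of correlation between genes alone. List members were also adjusted over the list alone, and where that count is not given it equals the count over all genes tested. The 34 lists, the tests of genes and lists, the alternatives except 1 and the rule for named genes were fixed before the data were examined. An added normexp fit, the test of gamma-delta T cells and the checks on arrays not used to choose the genes came after. The list of 5 loci linked to DNA methylation was written from memory and has not been checked against a source. Several probes were kept for 3457 genes, and in 70, 65 and 2 of these, for Th1 against naive, Th17 against naive and Th17 against Th1, probes passed in opposite directions.

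Genes were named by rule. In each comparison these were the 10 largest rises and the 10 largest falls among called genes with a symbol whose 3 arrays of one group all lay above those of the other and which were above background on all arrays of the higher group, up to 4 members of each list by smallest p, all members of the Th1, Th17, naive, sort gene, methylation machinery and methylation-linked lists, and single genes including Ifng, Il17a, Cd4, Cd3e, Ptprc and Tbx21. Some genes that the rule names are not reported here. Foxp3 and Gata3 were added after their values were seen, and so were the changes against naive cells of Aqp3, Wnt3, Ctsw, Nr4a2, Stat3 and Sh2d1a, which the rule had named between Th17 and Th1 cells.

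The alternatives were normexp background correction (offset 50), quantile normalization, the 75th percentile over probes above background on all arrays, the deposited table, no detection filter, detection on all 9 arrays, the mean of a gene's probes, every probe on its own, slide as a fixed or random block, fits within slide 1 and within slide 2, a replicate block, fits of 2 groups alone, trended and robust moderation, array weights, stricter thresholds and leaving out each array. The mean spot signal was not in the files, so normexp used the median signals. With slide as a fixed block, each group on each slide had its own fitted mean. Its change of Th1 against naive cells was therefore that of Th1 replicate 1 against the naive arrays, the estimate within slide 1. Its change of Th17 against Th1 cells was the estimate within slide 2. These paired fits differ only in the spread and are not separate checks. The blocked change of Th17 against naive cells was the sum of these 2, to which Th17 replicate 3, alone on slide 3, added nothing. On simulated data with 200 of 19071 genes changed, the fit recovered 57% to 69% of 2-fold and 88% to 92% of 4-fold changes with 8 to 11 false calls, and a planted list was found in all 3 comparisons. Noise was drawn independently for each gene and every member of the planted list was raised, so that result does not carry over to lists of correlated genes. Far fewer genes changed than were called in the data, so the recovery and the false calls need not hold there.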

Results

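The 9 arrays measured RNA of CD4+ T cells taken from spleen and lymph nodes of BALB/c mice and sorted by flow cytometry into 3 populations. Naive cells were sorted as CD45RB high, a surface form of the phosphatase CD45 that is lost on antigen experience. The other 2 populations were CD45RB low and were told apart by the cytokine captured on their surface. Th1 cells carried interferon gamma and no IL-17A, and Th17 cells carried IL-17A and no interferon gamma. All 3 populations had been stimulated for 3 h with the phorbol ester PMA (10 ng/ml) and the calcium ionophore ionomycin (500 ng/ml) before sorting, so the naive cells are stimulated cells too. Each population had 3 arrays. Between 53.4% and 58.3% of the probes on each array were well above background. The labels do not say which animals or sorts lie behind the replicates, so p-values measure only the spread between these samples, which may be technical. Levels below are log2 intensities relative to the 75th percentile of the array, and changes are log2 fold changes ± SE from limma with 3 arrays per group. Adjusted p-values follow Benjamini-Hochberg over the 19071 genes tested, of which 13080 had a gene symbol.

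The sorted cytokines followed the gates. The level of Ifng, the gene for interferon gamma, was 9.12 ± 0.18 (SD, n = 3) in Th1 cells, 1.72 ± 0.48 (SD, n = 3) in Th17 cells and 1.42 ± 0.17 (SD, n = 3) in naive cells. The level of Il17a was 9.24 ± 0.24 (SD, n = 3) in Th17 cells, -0.77 ± 1.5 (SD, n = 3) in Th1 cells and -3.03 ± 2.43 (SD, n = 3) in naive cells. Since the gates selected on these proteins, both differences check the labels and are no findings. Tbx21, which encodes the Th1 regulator T-bet, lay within 1 log2 unit in all 3 populations, at 4.91 ± 0.16 (SD, n = 3) in Th1, 4.76 ± 0.26 (SD, n = 3) in naive and 4.30 ± 0.18 (SD, n = 3) in Th17 cells. Its change in Th17 against naive cells, -0.46 (adjusted p = 0.0408), was no longer called without naive replicate 1 or 2 or Th17 replicate 1 or 3 (adjusted p between 0.058 and 0.129). Ptprc, the gene of CD45, did not pass the test in any comparison, at -0.17 ± 0.19 for Th1 against naive (adjusted p = 0.477) and -0.12 ± 0.19 for Th17 against naive (adjusted p = 0.624), although the gates differ in the CD45RB form. Cd3e, a chain of the T cell receptor complex, was 2.20 ± 0.15 higher in Th1 (adjusted p = 1.24e-05) and 1.63 ± 0.15 higher in Th17 (adjusted p = 5.52e-05) than in naive cells. Cd4 was 0.88 ± 0.14 higher in Th1 than in naive cells (adjusted p = 0.00109), and its 0.37 ± 0.14 in Th17 against naive cells missed the threshold (adjusted p = 0.0566), though not without Th17 replicate 3 (0.46, adjusted p = 0.033). A second, dimmer Cd4 probe gave 0.89 in that comparison (adjusted p = 0.000622), so the 2 probes differ on it. In Th17 against Th1 cells Cd4 was at -0.51 (adjusted p = 0.0445; -0.85 by the second probe, adjusted p = 0.00348), a call that ended without any single Th1 array or without Th17 replicate 2 or 3 (adjusted p between 0.0526 and 0.114). Cd3e was at -0.57 (adjusted p = 0.0391), a call that ended without Th1 replicate 1 or 2 or any single Th17 array (adjusted p between 0.0654 and 0.109).

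**Figure D1:**
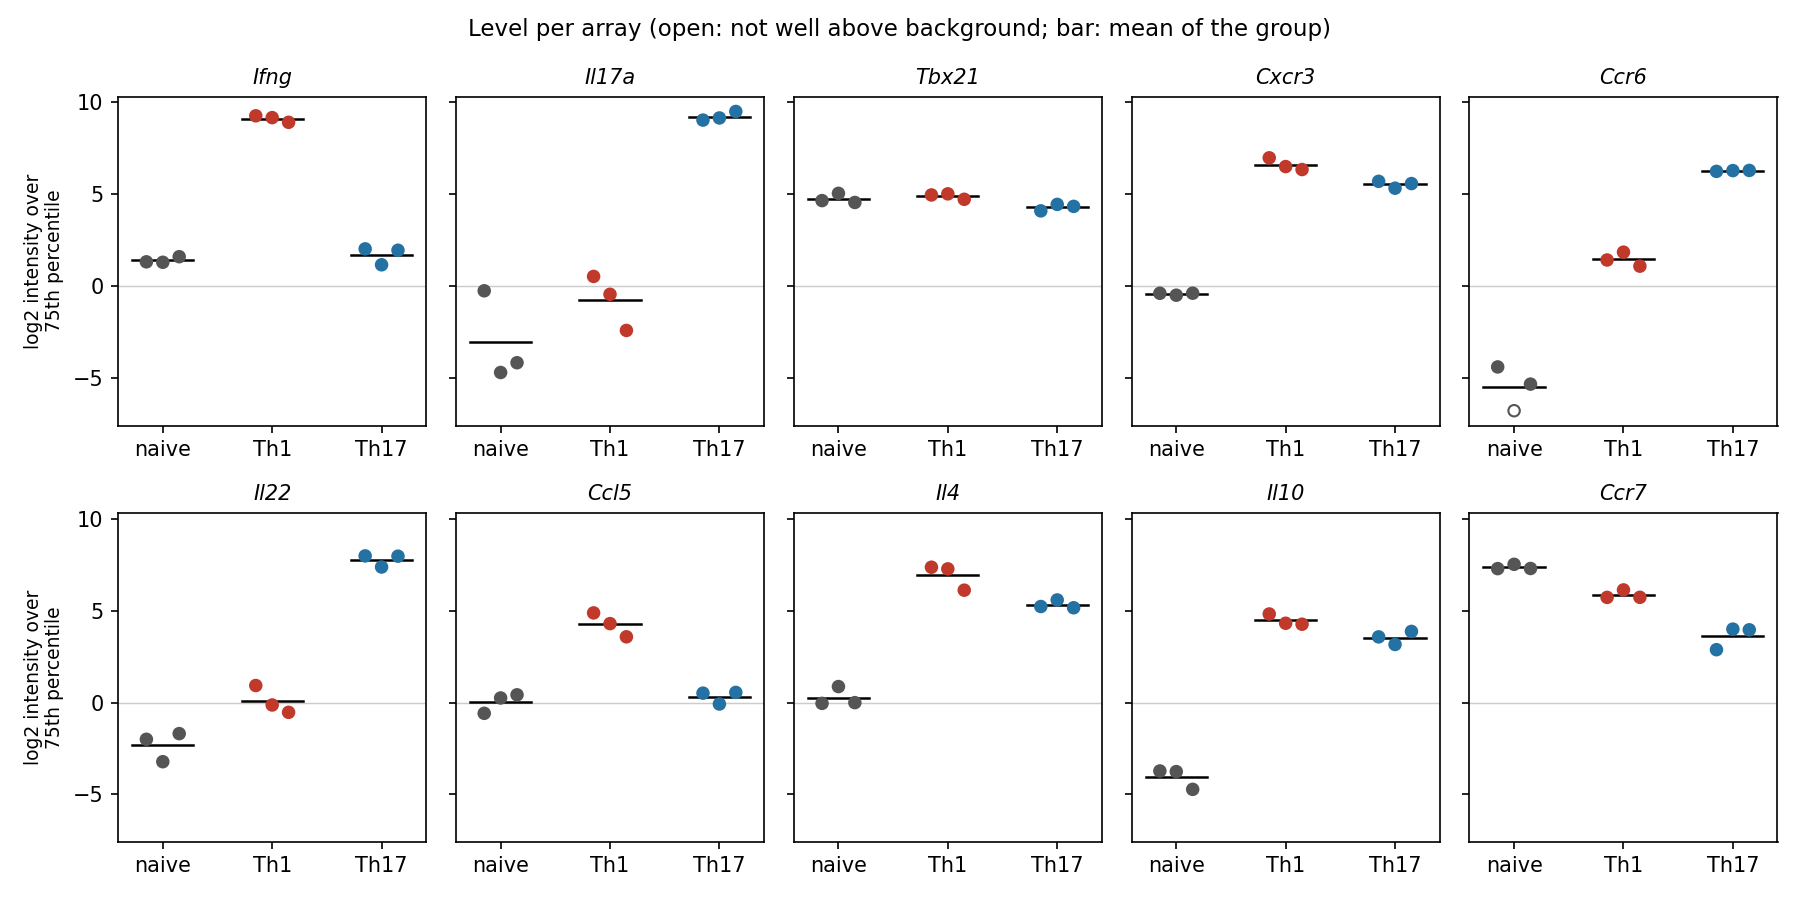
Level of 10 genes on each of the 9 arrays (y axis, log2 intensity relative to the 75th percentile of the array), by sorted population (x axis); each point is 1 array and each bar the mean of 3. Ifng stands at 9.12 in Th1 cells and Il17a at 9.24 in Th17 cells, while Tbx21 lies between 4.30 and 4.91 in all 3 populations.

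Th1 cells were compared with naive cells, both after the 3 h of stimulation. Th1 and Th17 cells differ from naive cells in CD45RB as well as in the captured cytokine. Changes against naive cells therefore cannot be assigned to cytokine secretion alone. Of the 19 measured genes of the Th1 list, which includes Ifng, 13 rose and 1 fell. Cxcr3, the receptor that brings Th1 cells to inflamed tissue, rose by 7.03 ± 0.17 (limma adjusted p = 1.17e-07). The chemokines Ccl4 and Ccl5 rose by 4.11 and 4.22. Stat4, which transmits IL-12 signals, rose by 2.97 and Il18r1, a chain of the IL-18 receptor, by 4.53. Runx3, a transcription factor that restrains Il4, fell by 1.30. Tbx21 was at 0.15 ± 0.16 (adjusted p = 0.462). The list as a whole lay above other genes (camera adjusted p = 1.88e-05, and adjusted p = 0.178 with an estimated correlation).

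All 11 measured inhibitory receptor genes were higher in Th1 than in naive cells (camera adjusted p = 4.25e-07, and adjusted p = 0.0327 with an estimated correlation). Ctla4, which competes with CD28 for its ligands, rose by 7.43 ± 0.37, Nt5e, the ectoenzyme CD73 that makes adenosine, by 4.79, Pdcd1, the gene of PD-1, by 4.31, and Lag3 by 3.69. Genes usually read as markers of other helper lineages were higher as well. In the Th2 list 7 of 9 rose (8 adjusted over the list alone; camera adjusted p = 0.000108, and adjusted p = 0.22 with an estimated correlation), with Il13 at 7.92 ± 0.69 and Il4 at 6.64 ± 0.37. Gata3, the Th2 regulator, named after its value was seen, was at 0.52 (adjusted p = 0.0519). In the regulatory T cell list 10 of 12 rose (adjusted p = 2.72e-06, and adjusted p = 0.162 with an estimated correlation). Ikzf2, the transcription factor Helios, rose by 8.84 ± 0.27 with 2 of 3 naive arrays above background, the cytokine Il10 by 8.53 ± 0.31 and Ebi3, a cytokine subunit, by 4.13. Foxp3, the regulator of that lineage, also named after its value was seen, rose by 3.97 ± 0.21. All 8 follicular helper genes rose (adjusted p = 1.89e-05, and adjusted p = 0.162 with an estimated correlation). The costimulatory receptor Icos rose by 4.15 and the cytokine Il21 by 3.56. Of the Th17 list 14 of 17 genes were higher in Th1 than in naive cells (adjusted p = 4.94e-06, and adjusted p = 0.237 with an estimated correlation). Ccr6 was at 6.95 with 2 of 3 naive arrays above background, Il17f at 5.79, Maf at 4.82 and Ahr at 4.31. Th17 cells within the sorted Th1 fraction could raise these genes. Such cells would bring Il17a in proportion, yet Il17a was 10.00 ± 1.15 lower in Th1 than in Th17 cells. Maf was only 0.98 and Ahr 1.11 lower. Ccr6 stood at 1.10 to 1.86 on the Th1 and at 6.25 to 6.30 on the Th17 arrays. For Maf, Ahr and Ccr6 these values argue against carried-over IL-17A producers as the whole source. The source of Il17f, and Th17 cells that make no Il17a, stay open. A member of the 14, Il1r1, was above background on no array of either population, and its call ended without naive replicate 2 or 3 or Th1 replicate 1 or 3 (adjusted p between 0.0702 and 0.116). Il17a was at 2.26 ± 1.15 (adjusted p = 0.131), or at 3.66 (adjusted p = 0.00561) without naive replicate 1. Genes of memory and migration rose in 16 of 20 cases and fell in 1 (adjusted p = 1.14e-06, and adjusted p = 0.273 with an estimated correlation). S100a4, a calcium-binding protein of motile cells, was at 6.11 and the chemokine receptor Cxcr6 at 5.80. Of 18 chemokine genes and receptors 14 rose and 2 fell (adjusted p = 7.36e-06, and adjusted p = 0.205 with an estimated correlation).

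In Th1 cells 13 of the 18 naive cell genes fell and 2 rose (14 fell adjusted over the list alone; camera adjusted p = 0.00121, and adjusted p = 0.178 with an estimated correlation). The transcription factor Lef1 fell by 2.52 and Ccr7, a lymph node homing receptor, by 1.51. Il7r, the receptor of the survival cytokine IL-7, rose by 1.99. The interferon response list was lower, with 12 of 17 down and 3 up (adjusted p = 0.00233, and adjusted p = 0.22 with an estimated correlation). Usp18, which removes ISG15 from proteins, fell by 4.85 ± 0.30, Irgm1, an interferon-inducible GTPase, by 3.63, and the guanylate-binding protein gene Gbp2 by 3.58. Cholesterol and fatty acid synthesis genes fell in 12 of 16 cases and rose in none over all genes tested (1 rose adjusted over the list alone; adjusted p = 0.00102, and adjusted p = 0.205 with an estimated correlation). Ribosomal protein genes were lower by small amounts, 25 of 28 passing with a median of -0.49 (27 adjusted over the list alone; adjusted p = 7.36e-06, adjusted p = 0.478 with an estimated correlation). The ribosomal call was lost under quantile normalization (median -0.10, adjusted p = 0.208). It passed with slide as a block (median -0.38, adjusted p = 0.00022) with 11 genes lower, and 4 were lower within slide 1. TGF-beta signalling genes fell in 7 of 11 cases (8 adjusted over the list alone; adjusted p = 0.0255, and adjusted p = 0.378 with an estimated correlation), with a median of -0.51. With slide as a block the median was -0.48 and the list no longer passed (adjusted p = 0.0715). Within slide 1 the same estimate, from 1 Th1 array, passed against another spread.

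The 10 largest rises in Th1 over naive cells held genes outside these lists. Penk, which encodes the opioid precursor proenkephalin, rose by 9.62 ± 0.38 and Nrn1, the membrane-anchored protein neuritin, by 9.62 ± 0.17. The chemokine Ccl1 rose by 9.22 ± 0.49. Some genes were well above background on none of the naive arrays, so that only a lower bound of their change can be given, the mean of the brighter group set against the lowest signal among probes above background. On this scale Gpm6b, a membrane glycoprotein, was at least 1040-fold, Ccn4 at least 875-fold, and the tyrosine phosphatase Ptpn5 at least 211-fold higher. The dicarboxylate transporter Slc13a3 was at least 193-fold, the secreted BMP antagonist Sostdc1 at least 119-fold and Scg2, a granin, at least 113-fold higher. Esm1 rose by 9.41 ± 0.62 with 1 of 3 naive arrays above background. Among the falls, Xkrx was at least 162-fold, the tubulin Tubb2b at least 54.5-fold, Khdrbs3 at least 23.8-fold, Dennd2c at least 14.9-fold and Glis2 at least 12-fold lower in Th1 cells. Plaur, the urokinase receptor, fell by 6.23 ± 0.33, the sodium pump subunit Atp1b1 by 5.71 ± 0.20 and Pdlim4 by 5.66 ± 0.56. Oasl1, an interferon-induced gene, fell by 6.07 and the heat shock gene Hspa1a by 5.43, each with 1 of 3 Th1 arrays above background, and Hspa1a varied widely over the naive arrays (SD 2.37, n = 3).

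By limma with an adjusted p under 0.05, 10288 genes differed between Th1 and naive cells, 4485 higher and 5803 lower. Changes of at least 2-fold were found for 3946 of them, with the opposite balance, 2211 higher and 1735 lower. With slide as a block 7893 genes passed. Within slide 1, which held the 3 naive arrays and 1 Th1 array, 6547 passed, with the spread taken from the naive arrays alone. In a check chosen after seeing the data, 9686 genes were called without that Th1 array, and 98.9% of them had the same direction in it, at 0.914 of the median size. The naive arrays were used in both steps. The median shifts of the inhibitory receptor and interferon response lists were 3.73 and -2.15 within slide 1 against 3.89 and -1.91 over all arrays. They were the same with slide as a block, whose change also rests on Th1 replicate 1 alone. Scaling to probes above background on all arrays moved the median of all genes from -0.093 to 0.055 and the share of higher calls from 43.6% to 55.2%. Small changes such as those of the ribosomal genes are relative to that scaling.

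**Figure D2:**
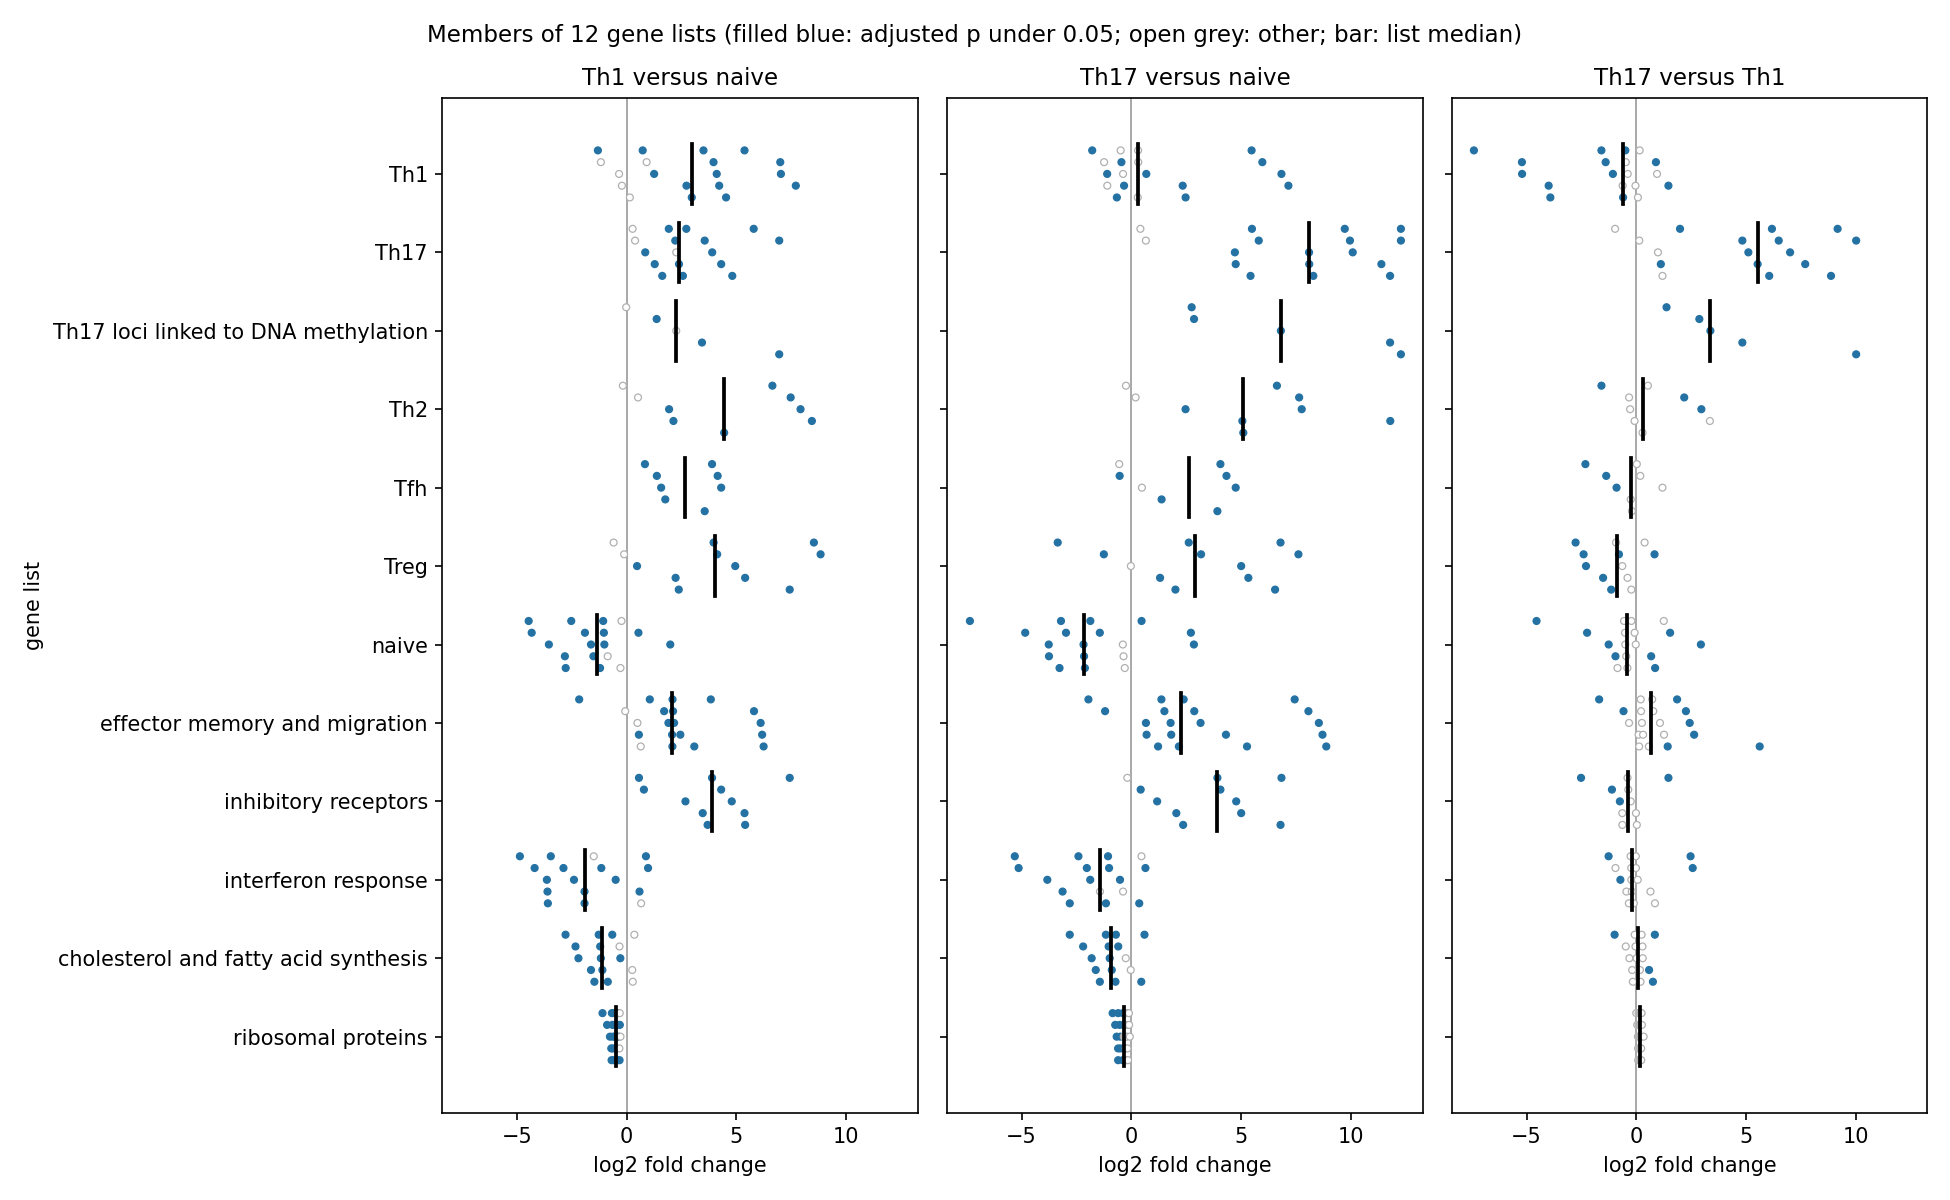
Log2 fold change (x axis) of each measured member of 12 gene lists (y axis) in Th1 against naive, Th17 against naive and Th17 against Th1 cells; each point is 1 gene, filled blue where its limma adjusted p was under 0.05 and open grey otherwise, and the bar is the list median; genes below background in a group are drawn at their fitted change. The Th17 list has its median at 2.39, 8.09 and 5.52 in the 3 comparisons, and the interferon response list at -1.91, -1.43 and -0.21.

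Th17 cells were compared with naive cells in the same way. Il17f, the close relative of Il17a, rose by 12.27 ± 0.73 (limma adjusted p = 5.28e-06) and Il22, a cytokine acting on epithelia, by 10.07 ± 0.47. Iltifb, a near-identical copy of Il22 whose probe may read the same transcript, was at least 272-fold higher and is uncertain for that reason. Ccr6, the receptor for CCL20, rose by 11.77 ± 0.51 with 2 of 3 naive arrays above background, the IL-23 receptor gene Il23r was at least 537-fold, the protease inhibitor Serpinb1a at least 651-fold and the IL-1 receptor gene Il1r1 at least 230-fold higher. Of the 17 measured genes of the Th17 list 15 rose and none fell (camera adjusted p = 6e-11, and adjusted p = 0.202 with an estimated correlation). The transcription factors Maf, Ahr and Rora rose by 5.79, 5.42 and 4.71, and the leukotriene receptor Ltb4r1 by 5.48. The list of 5 loci linked to DNA methylation in Th17 cells was written from memory and has not been checked against a source. Its members Il17a, Ccr6, Acsbg1, Dpp4 and Zfp362 all rose in Th17 cells (adjusted p = 0.000123, and adjusted p = 0.183 with an estimated correlation). They may have been picked on cells of this sort, so the count is no independent evidence of their direction. Acsbg1, an acyl-CoA synthetase, rose by 6.80 ± 0.35 with 2 of 3 naive arrays above background, Zfp362 by 2.85 ± 0.15 and Dpp4, the peptidase CD26, by 2.74 ± 0.17.

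The Th1 list did not move as a whole in Th17 cells, with 7 of 19 genes higher and 5 lower than in naive cells (camera adjusted p = 0.228, and adjusted p = 0.61 with an estimated correlation). Cxcr3 rose by 5.96 ± 0.17 and Stat4 by 2.46, while Ifng was at 0.31 ± 0.23 (adjusted p = 0.289) and Ccl4 was at -1.11 (adjusted p = 0.0357), a call that ended without naive replicate 2 or 3 or any single Th17 array (adjusted p between 0.0505 and 0.114). Memory and migration genes rose in 18 of 20 cases and fell in 2 (adjusted p = 3.53e-07, and adjusted p = 0.289 with an estimated correlation). Anxa1, an annexin, was at 8.87 with 2 of 3 naive arrays above background, the galectin Lgals3 at 8.70, S100a4 at 8.53 and Cxcr6 at 8.06. Inhibitory receptors rose in 10 of 11 cases (adjusted p = 2.32e-05, and adjusted p = 0.0882 with an estimated correlation). Havcr2, the gene of TIM-3, was at 6.83 and Ctla4 at 6.79. As in Th1 cells, Th2 genes rose in 7 of 9 cases (adjusted p = 0.000157, and adjusted p = 0.246 with an estimated correlation). Il5, the eosinophil growth factor, was 11.78 ± 1.37 higher with 1 of 3 naive arrays above background, Il4 5.05, the epidermal growth factor receptor ligand Areg 6.62 and the chemokine receptor Ccr4 5.09. Regulatory T cell genes rose in 9 of 12 cases and fell in 2 (adjusted p = 0.000468, and adjusted p = 0.215 with an estimated correlation). Il10 rose by 7.60, Ikzf2 by 6.54, Ebi3 by 2.61 and Foxp3 by 3.17. Cytokine genes beyond these lineages rose in 17 of 23 cases and fell in 2 (3 fell adjusted over the list alone, adjusted p = 1.54e-05, and adjusted p = 0.202 with an estimated correlation). Tnfsf11, the osteoclast factor RANKL, rose by 5.89 and Tnfsf14 by 4.33.

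In Th17 cells 12 of 18 naive cell genes fell and 3 rose (camera adjusted p = 0.00149, and adjusted p = 0.202 with an estimated correlation). Ccr7 was at -3.76 ± 0.29 and S1pr1, which lets T cells leave lymph nodes, at -2.12. Of the interferon response genes 12 of 17 fell and 2 rose (adjusted p = 0.00149, and adjusted p = 0.22 with an estimated correlation), with Usp18 at -5.31 and Isg15, a ubiquitin-like modifier, at -3.14. Of the cholesterol and fatty acid synthesis genes 12 of 16 fell and 2 rose (adjusted p = 0.000912, and adjusted p = 0.217 with an estimated correlation). The ribosomal list had 16 of 28 genes lower with a median of -0.32 (17 adjusted over the list alone; adjusted p = 0.000734, and adjusted p = 0.61 with an estimated correlation). That was a call lost under quantile normalization (adjusted p = 0.233). It passed with slide as a block (median -0.20, adjusted p = 0.0277) but 0 of its 28 genes were called. The largest falls included Atp1b1 at -7.59 ± 0.20 and the actin-binding calponin Cnn3 at -5.99 ± 0.16. The T-box factor Eomes was at -5.70 ± 0.64 and Igsf3 at -5.67 ± 0.43, each with 1 of 3 Th17 arrays above background. Dapl1 was at least 46.4-fold, the adhesion protein Amigo2 at least 21.9-fold, the tight junction protein Cgn at least 13.6-fold, the kinase Dapk1 at least 13.2-fold, Arhgap29 at least 12.5-fold and Zfp354c at least 11.4-fold lower.

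Between Th17 and naive cells 10332 genes passed the test, 4661 higher and 5671 lower. The balance turned among the 4236 changes of at least 2-fold, 2262 higher and 1974 lower, and under scaling to probes above background on all arrays, where 51.5% of calls were higher. No slide held both populations, so no value within a slide exists. With slide as a block, bridged by the Th1 arrays on 2 slides, 5242 genes passed, 4869 of them among the 10332, of which 99.2% kept their direction, and 52.4% of the 5242 were higher. The medians of the Th17 and interferon response lists were then 9.06 and -1.66.

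Both comparisons share the 3 naive arrays. In both, 7950 genes passed in one direction, 3430 higher and 4520 lower, against 1096.1 and 1725.6 for independent lists. Arrays simulated with no change against the same controls gave 0.1 such genes on average over 20 draws, a count of false calls that does not measure what shared controls add to the overlap of changed groups. Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.817 (0.504 in the simulation) and a covariance of 1.23 (0.0473 in the simulation). The simulated covariance is what noise of the shared naive arrays adds, and it was small against the observed one. A trait common to the 3 naive arrays was not simulated. These arrays were too few to split, so what they add to the shared count stays open. A further 129 genes passed in opposite directions, of which 6 had a comparison in which no array of either group was above background. Passing in Th1 alone were 2209 genes, of which 672 also differed between Th17 and Th1 cells, and in Th17 alone 2253, of which 842 did.

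**Figure D3:**
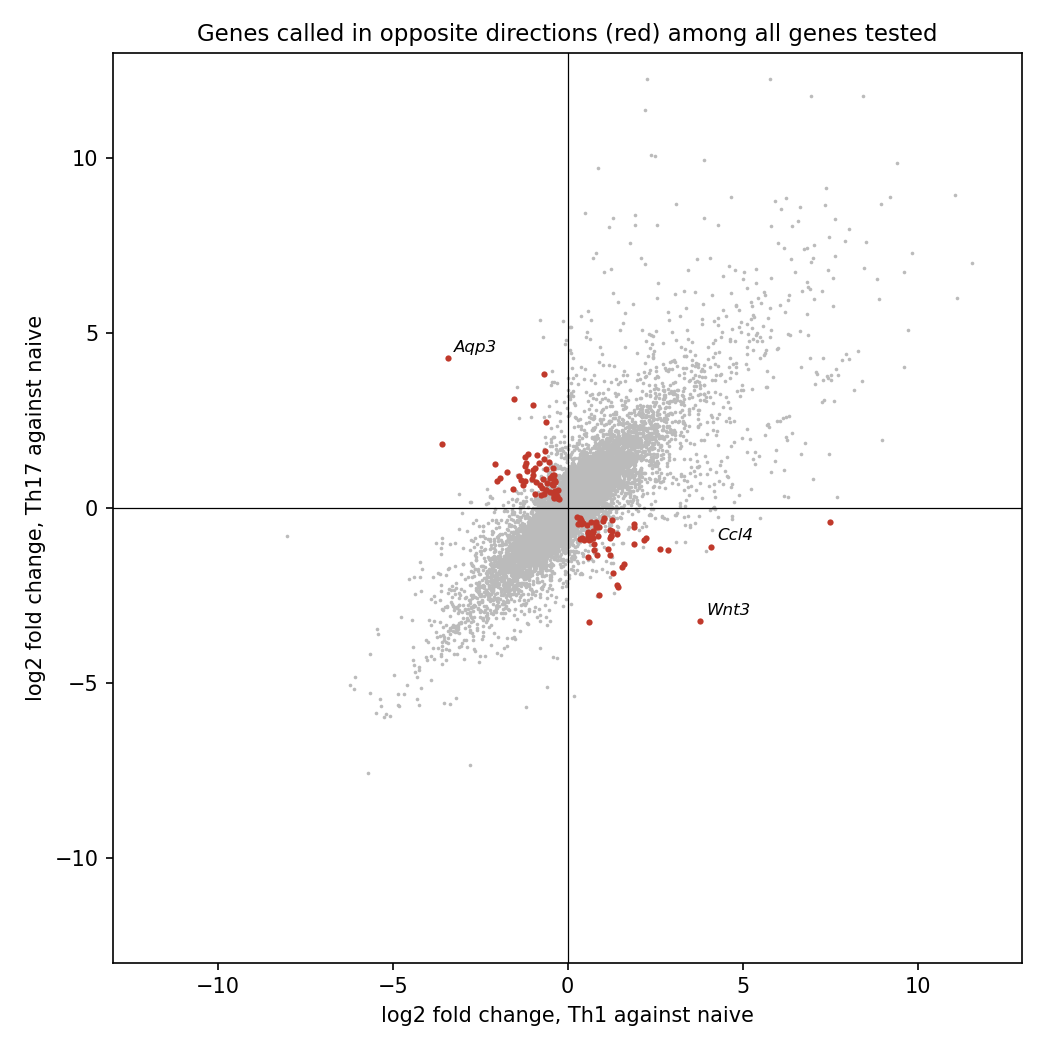
Log2 fold change of the 19071 genes in Th1 against naive (x axis) and in Th17 against naive cells (y axis), each point 1 gene; the 129 genes that passed in opposite directions are in red, and Aqp3, Wnt3 and Ccl4 are labelled. The fold changes have a Pearson r of 0.817, and Aqp3 lies at -3.42 and 4.28.

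The direct comparison of Th17 with Th1 cells separated the lineages. In the Th17 list 13 of 17 genes were higher in Th17 cells and none lower (15 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.1e-12, and adjusted p = 0.255 with an estimated correlation). Il17a was higher by 10.00 ± 1.15, Il23r by 9.16 ± 0.54 with 2 of 3 Th1 arrays above background, Il22 by 7.68 ± 0.47, Il17f by 6.48 ± 0.73 and Ccr6 by 4.82 ± 0.51. Il1r1 was at least 221-fold higher, and Iltifb, with the limit given above, was higher by 7.55 with 2 of 3 Th1 arrays above background. All 5 loci linked to methylation were higher, Acsbg1 by 3.36, Zfp362 by 2.86 and Dpp4 by 1.37 (adjusted p = 3.22e-06, and adjusted p = 0.15 with an estimated correlation). This list holds Il17a, on which the cells were sorted. With the limits given above, its direction is no independent evidence here either. Zfp362 was at -0.015 ± 0.15 in Th1 against naive cells (adjusted p = 0.942). Further genes that were higher in Th17 cells were Aqp3, a water and glycerol channel, by 7.70 ± 0.32 with 1 of 3 Th1 arrays above background, and Lingo4 by 6.85 with 2 of 3. Xkrx was at least 92.6-fold and Pxdc1 at least 78.9-fold higher. Lgals3 was higher by 5.61, Ccr4 by 2.95, Ccr9, a gut homing receptor, by 2.93 and Cxcr6 by 2.25. The memory and migration list was higher in 6 of 20 cases and lower in 2 (9 and 2 adjusted over the list alone; adjusted p = 0.00463, and adjusted p = 0.618 with an estimated correlation). Its median was 0.64, and with slide as a block 1.05, where 12 were higher and 1 lower.

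Th1 list genes were lower in Th17 cells in 10 of 19 cases and higher in 2 (11 and 2 adjusted over the list alone; camera adjusted p = 6.29e-05, and adjusted p = 0.255 with an estimated correlation). Ifng was at -7.40 ± 0.23. The chemokines Ccl3, Ccl4, Xcl1 and Ccl5 changed by -5.21 ± 0.68, -5.21 ± 0.38, -4.00 ± 0.68 and -3.92 ± 0.38. The granule protein gene Nkg7 changed by -1.60, or by -4.40 on its second probe, and the death receptor ligand Fasl by -1.40. Cxcr3 differed less, at -1.07 ± 0.17 (adjusted p = 0.0046), and Tbx21 at -0.61 ± 0.16 (adjusted p = 0.0374), a call that ended on leaving out Th1 replicate 1 or 2 or any single Th17 array (adjusted p between 0.0517 and 0.121). Regulatory T cell genes were lower in 6 of 12 cases and higher in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.00117, and adjusted p = 0.308 with an estimated correlation). Izumo1r, a folate receptor family gene, was at -2.41 and Ikzf2 at -2.30. Among the inhibitory receptors Lag3 was at -2.52 ± 0.20. In the STAT3 and IL-6 family list 6 of 13 genes were lower and 1, Il23r, was higher (9 and 3 adjusted over the list alone; adjusted p = 0.0318, and adjusted p = 0.618 with an estimated correlation). The lower ones included Stat3 at -1.54 ± 0.21, the receptor subunit Il6st at -1.72 ± 0.29 and the IL-21 receptor gene Il21r at -1.51 ± 0.18. Its median was -0.96, and with slide as a block -0.70, where the list no longer passed (adjusted p = 0.0959). Other large differences toward Th1 cells were Nrn1 at -5.60 ± 0.17, Sostdc1 at -7.07 and Sh3rf2 at -6.18 with 1 of 3 Th17 arrays above background each, and Stfa3, of a family of similar genes, at -5.95 with 2 of 3. Actbl2, which resembles the other actin genes, was at least 50.6-fold, the signalling protein Wnt3 at least 48.8-fold and Col24a1 at least 12.2-fold lower in Th17 cells.

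Of the marker lists of other cells none passed against naive cells over all arrays. The erythroid list did for Th1 cells within slide 1 (median 3.03 against 2.05), where the spread came from the naive arrays beside 1 Th1 array. With slide as a block its median was the same, 0 of its genes were called and it did not pass (adjusted p = 0.369). Between Th17 and Th1 cells only the gamma-delta T cell list passed. In that list, the scavenger receptor gene 5830411N06Rik was higher in Th17 than in Th1 cells by 6.44 ± 0.48 with 1 of 3 Th1 arrays above background, and Cd163l1 was at least 5.68-fold higher, while Sox13 was at 0.046 (list adjusted p = 0.0153, and adjusted p = 0.371 with an estimated correlation). In the NK cell list, which had 3 measured genes and did not pass (adjusted p = 0.742), Klrc1 was at least 28.6-fold higher in Th17 than in Th1 cells, Eomes was at -4.50 with 1 of 3 Th17 arrays above background, and Klra1 at 0.78 (adjusted p = 0.562). Cd8b1, of the CD8 lineage, was lower than in naive cells by 3.31 ± 0.16 in Th1 and by 3.41 ± 0.16 in Th17 cells, and H2-Ab1, an MHC class II gene of B cells, was at -2.78 and -2.64. In the erythroid list 3 of 4 measured genes were called higher in Th17 than in naive cells, with a median of 4.06, and 0 were called with slide as a block. The hemoglobin gene Hba-a1, whose copies share sequence, was 4.49 ± 1.22 higher in Th17 than in naive cells (adjusted p = 0.0138). In Th1 cells it varied with an SD of 2.78 over 3 arrays, its change against naive cells being 2.46 (adjusted p = 0.122), or 4.04 (adjusted p = 0.00194) without Th1 replicate 3.

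In total 3015 genes differed between Th17 and Th1 cells, 1579 higher and 1436 lower in Th17, 1220 of them by at least 2-fold, 587 higher and 633 lower. With slide as a block 2145 genes passed. Within slide 2, which held 2 arrays of each population, 1419 passed, with a Th17 list median of 6.11 against 5.52. Without slide 2, 1 Th1 and 1 Th17 array remain, with the spread taken from the naive arrays alone. Of the 1203 genes called on these, a check also chosen after seeing the data, 83.1% had the same direction within slide 2, at 0.464 of the median size. Without Th1 replicate 2 the count was 1924, and scaling to probes above background on all arrays changed the share of higher calls from 52.4% to 41.6%.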

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

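The test of gamma-delta T cells within the Th17 fraction was chosen only after the result was seen. Among the genes chosen by rule, and leaving out Actbl2, which was above background on no naive or Th17 array, 9 passed in opposite directions in Th1 and in Th17 cells against naive cells, and the difference between Th17 and Th1 cells passed the limma test for each. Aqp3, with 1 of 3 Th1 arrays above background, differed by 7.70. Wnt3, above background on no Th17 array, rose by 3.78 in Th1 and was at least 3.56-fold lower in Th17 than in naive cells and at least 48.8-fold lower than in Th1 cells. Its fitted difference of -7.02 rests on signal below background and is no measured size. The differences were -5.21 for Ccl4, -2.07 for the cathepsin gene Ctsw, -1.81 for the nuclear receptor gene Nr4a2, -1.60 for Nkg7, -1.54 for Stat3, -1.40 for Fasl and -1.38 for the adaptor gene Sh2d1a. In Th17 against naive cells the calls of Ccl4 and Nkg7 each ended without naive replicate 2 or 3 or any single Th17 array. The adjusted p was then between 0.0505 and 0.114 for Ccl4 and between 0.0567 and 0.11 for Nkg7, whose second probe gave -0.13 there (adjusted p = 0.78). The call of Ctsw ended without any single naive array or Th17 replicate 2 or 3 (adjusted p between 0.0628 and 0.117), and with slide as a block its change turned to 0.34. The call of Sh2d1a ended without any single naive array or Th17 replicate 1 or 2 (adjusted p between 0.0822 and 0.143). In Th1 against naive cells the call of Stat3 ended without naive replicate 1 or 3 or any single Th1 array (adjusted p between 0.0557 and 0.116). The opposite directions of these 5 genes are therefore uncertain.

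The first pattern is the size of the 3 counts, 10288, 10332 and 3015 genes. Each comparison allows 10 splits of its 6 arrays into 3 and 3. The real split alone reached its count, so 1 of 10 did, and the highest of the other splits called 1 gene in each comparison, but 10 splits are too few for a share under 0.05. A mixed split also puts the group difference into its own spread. Its low count therefore follows from any strong group difference and is no measure of chance. Slide may add to the counts, since it is partly confounded with the groups, but as their whole cause it would have shrunk the changes. The median signed change of the called genes within slide 1 was 0.971 of that over all arrays for Th1 against naive cells, with slide as a block 0.932 for Th17 against naive cells, and within slide 2 0.959 for Th17 against Th1 cells. The Th1 array of slide 1 and the arrays of slide 2 were also among those the calls came from, so these ratios are not independent. For genes chosen without the Th1 array of slide 1 the ratio in that array was 0.914. For the 1203 genes chosen without slide 2, from 1 Th1 and 1 Th17 array, the ratio within slide 2 was 0.464. A choice on single arrays lowers such a ratio by itself, so it does not show whether slide enlarged the changes, which stays open. Slide as the whole cause is still excluded there, since 1419 genes passed within slide 2. Differences between animals or sorts stay open and untested.

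The second pattern is the gamma-delta T cell list in Th17 cells, with 5830411N06Rik and Cd163l1 higher. Gamma-delta T cells that secrete IL-17A may be present in the fraction, although the CD3+CD4+ gate would remove cells without CD4. Such cells would lower Cd4 relative to Cd3e, and that difference between Th17 and Th1 cells was 0.0587 on the log2 scale (SE 0.131, 95% interval -0.26 to 0.38). With the second Cd4 probe it was -0.28 (SE 0.134, 95% interval -0.61 to 0.045), the direction such cells would give. The intervals allow up to 16.6% and 34.6% of cells without Cd4, so these cells and expression by Th17 cells cannot be told apart. The third member of the list, Sox13, was at 0.046 with an adjusted p of 0.849, and Klrc1 and Cd163l1 were above background on no Th1 array.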

How the results depend on the processing

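The normexp fit without background-outlier spots was chosen after seeing the data. Gene counts, list counts and the shared count stayed within 1.5 times their value under the settings not named here. The planned normexp fit gave 1248, 1230 and 175 genes for Th1 against naive, Th17 against naive and Th17 against Th1, and 774 shared genes. In it 5 spots of Th1 replicate 2 had a local background of up to 168530. Without the background-outlier spots of all arrays, 16 on that array, the counts were 9342, 9293, 2904 and 7105; the 5 spots were not tested alone. Under the planned normexp fit these log2 changes turned: in Th1 against naive Dnmt1 to 0.077, Foxp1 to -0.11 and Stat3 to -0.034, in Th17 against Th1 Cd4 to 0.0055, Cd3e to 0.093, Tbx21 to 0.00, Cd74 to -0.12, Smad4 to 0.12, Tgfbr2 to 0.10, Stat4 to 0.11, Ccna2 to -0.19, Klrk1 to -0.20 and Pfkp to 0.10. Without the outlier spots Il1r1, below background in both groups, turned to -0.12 in Th1 against naive. With slide as a fixed block Th17 against naive gave 5242 genes, 4381 were shared and Tnf turned to -0.029 and Ctsw to 0.34 in Th17 against naive, where 38 of 191 named genes lost their call, as did 8 of 201 in Th1 against naive and 27 of 186 in Th17 against Th1; within slide 1 6547 genes passed in Th1 against naive, and within slide 2 1419 in Th17 against Th1, with fewer arrays in the fit. The fixed block leaves Th17 replicate 3 out of the change of Th17 against naive cells, so calls lost there may come from fewer arrays. As a random block, with a correlation of 0.25, slide gave 9697, 8998 and 3206 genes. The requirement of 2-fold changes left 3946, 4236 and 1220 genes and 2884 shared, and an adjusted p under 0.01 left 1394 in Th17 against Th1, both by construction. With an estimated correlation 1, 0 and 0 lists passed camera. For the inhibitory receptors the estimate of -0.0118 lay below the preset 0.01. Their unadjusted camera p in Th1 against naive cells still rose from 1.29e-08 to 0.000992, so a larger correlation is not the only reason. The stress list, with an estimate of -0.0384, also rose in that comparison, from an unadjusted camera p of 0.0396 to 0.076. Lists lost with the estimate therefore do not show that correlation between genes alone removed them. What else the estimated setting changed was not tested. Leaving out 1 array gave 8662 to 9686, 8816 to 10162 and 1924 to 2572 genes and 6586 to 8202 shared, with fewer samples. A replicate block gave 10165, 10286 and 3037. Of the list calls in Th17 against Th1, those of the Th1, Th17, methylation-linked, regulatory T and memory lists passed under every setting at the preset correlation. The Th1 list holds Ifng and the methylation-linked list Il17a, so the sort fixed part of their direction under any setting. The 7 others were lost under at least 1, and of these the inhibitory receptor and sort gene lists turned direction under the planned normexp fit. The ribosomal calls were lost under quantile normalization in all 3 comparisons and the TGF-beta calls with slide as a block; the cause was not tested for these, for Tnf, Ctsw or Il1r1. Signal over background limits the bounds given for dim genes.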

Other observations

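Enzymes that write, read or remove DNA methylation moved singly. Tet2, which oxidises methylcytosine, rose by 1.74 in Th1 and by 0.91 in Th17 against naive cells, and was at -0.83 in Th17 against Th1. Mbd2, a reader of methylated DNA, rose by 1.13 in Th17 cells, and Gadd45a, linked to active demethylation, fell by 2.21 in Th1 and by 2.91 in Th17 cells. The methyltransferase Dnmt3b fell by 0.43 and by 0.68. Of the 15 genes of this list 2 rose and 4 fell in Th1, and 2 rose and 5 fell in Th17 cells (1 and 4, and 2 and 5, adjusted over the list alone; adjusted p = 0.902 and 0.603). Early activation genes moved both ways. Cd69, a marker of recent activation, fell by 2.45 in Th1 and by 2.05 in Th17 cells, and Fosb and Fos fell by 2.10 and 2.36 in Th17 cells. The early activation list had 6 up and 5 down of 23 in Th1 (5 and 5 adjusted over the list alone; adjusted p = 0.807) and 5 up and 12 down in Th17 (5 and 13 adjusted over the list alone; adjusted p = 0.193). With slide as a block the latter were 3 up and 4 down, with a median of -0.24 against -0.61.

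Over all genes tested, 53.95% were called in Th1 and 54.18% in Th17 against naive cells, and 15.81% in Th17 against Th1 cells. Counts of list members stand against these shares, which hold both directions. Of the 19071 genes, 4485 were higher and 5803 lower in Th1, and 4661 and 5671 in Th17 against naive cells. In Th17 against Th1 cells 1579 were higher and 1436 lower. Glycolysis genes fell in 8 of 15 cases and rose in 2 in Th1 cells (9 fell adjusted over the list alone, adjusted p = 0.115). In Th17 cells 6 fell and 3 rose (adjusted p = 0.228), and Hk1, a hexokinase, was at -2.02 in Th1 and -1.87 in Th17 cells. The falls were 4 and 2 with slide as a block. The death gene Bcl2l11, which encodes BIM, fell by 1.81 and 1.53, and the apoptosis list had adjusted p = 0.0539 and 0.161. In Th1 cells it passed with slide as a block (median -0.58 against -0.54, adjusted p = 0.0357). It passed within slide 1 as well, which is the same estimate from 1 Th1 array and no second check. Proliferation genes moved both ways, with Mki67 at 2.50 and 3.50 and Pcna at -0.45 and -0.65, and the cell cycle list had adjusted p = 0.807 and 0.439. The stress list had adjusted p = 0.0726 and 0.0919, the cytotoxicity list 0.132 and 0.955, and the STAT3 list 0.902 and 0.229 against naive cells. Of these the cytotoxicity list passed in Th1 cells with slide as a block (median 1.08 against 0.65, adjusted p = 0.0483). It also passed within slide 1, again the same estimate from 1 Th1 array. Chemokine genes rose in 11 of 18 cases and fell in 3 in Th17 cells (adjusted p = 0.00234, and adjusted p = 0.335 with an estimated correlation). Follicular helper genes rose in 5 of 8 cases and fell in 1 (adjusted p = 0.00769, and adjusted p = 0.246 with an estimated correlation). TGF-beta genes fell in 8 of 11 cases and rose in 1 (adjusted p = 0.0292, and adjusted p = 0.459 with an estimated correlation). For these 0 of the 11 were called with slide as a block, and the list no longer passed (median -0.41 against -0.70, adjusted p = 0.0677). Cytokines beyond the lineage lists rose in 14 of 23 cases and fell in 3 in Th1 cells (adjusted p = 0.000285, and adjusted p = 0.205 with an estimated correlation). The list of sort genes holds Ifng and Il17a, whose differences are fixed by the sort and are no findings, so its test is partly fixed as well. The list also holds other genes of the gated proteins, such as Cd4 and Cd3e, whose gates did not tell the populations apart. It passed in all 3 comparisons, at adjusted p = 0.00201, 0.0372 and 0.0318 (adjusted p = 0.275, 0.519 and 0.602 with an estimated correlation). The last of these calls was lost with slide as a block (median -0.30 against -0.51, adjusted p = 0.0959). It was also lost within slide 2, where the estimate is the same (adjusted p = 0.198). The methylation-linked loci passed in Th1 cells at adjusted p = 0.0214 (adjusted p = 0.22 with an estimated correlation).

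Between Th17 and Th1 cells further lists passed at the preset correlation: cell cycle (adjusted p = 0.0463), ribosomal proteins (adjusted p = 0.0153, with 0 of 28 genes called), other cytokines (adjusted p = 0.0153) and inhibitory receptors (adjusted p = 0.0474). With an estimated correlation they had adjusted p = 0.602, 0.786, 0.539 and 0.308. The ribosomal list no longer passed camera under quantile normalization (median 0.0011 against 0.15, adjusted p = 0.915). Under normexp without background-outlier spots it did not pass either (adjusted p = 0.179). The cell cycle list no longer passed with slide as a block (median 0.35 against 0.40, adjusted p = 0.201) or within slide 2 (the same estimate, adjusted p = 0.132). The follicular helper list, at adjusted p = 0.124 over all arrays, passed with slide as a block (median -0.40 against -0.23, adjusted p = 0.0401). It passed within slide 2 with the same estimate (adjusted p = 0.0215). Gbp2 and Irgm1 were higher in Th17 than in Th1 cells by 2.56 and 2.46, while the interferon response list had adjusted p = 0.766.

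Markers of other cells are given as values. Vcam1, an adhesion gene of stromal cells, was at least 92.7-fold higher in Th1 and at least 30.2-fold higher in Th17 than in naive cells, and the myeloid gene Cd14 rose by 3.06 in Th17 cells. In Th1 against naive cells the B cell, myeloid, neutrophil, dendritic cell, NK cell, gamma-delta T, erythroid, platelet and stromal lists had camera adjusted p = 0.667, 0.494, 0.704, 0.807, 0.902, 0.902, 0.353, 0.494 and 0.374. In Th17 against naive cells they had 0.404, 0.348, 0.488, 0.75, 0.626, 0.194, 0.137, 0.689 and 0.236. The CD8 list had 1 measured gene and no list test. In a principal component analysis the first component held 62.3% and the second 18.8% of the variance.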
